A study of Mus musculus with 6 samples.

How the data were processed

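The series compares C2C12 mouse myoblasts with PRDM2 knocked down against GFP shRNA controls after 48 hours in methylcellulose suspension, with 3 arrays per group. The labels call the samples of a group biological replicates of a stable pool, and do not say whether they came from separate transfections. Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 8 µg of it for Affymetrix arrays. The deposited values are 1 intensity per probe set and array on a linear scale. GCOS and PLIER are named in the submitters' processing notes, without versions. How background was corrected and whether arrays were normalized to each other is not given in the sources used here. The table held 45101 probe sets and 0 columns of other samples.

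All values were analysed in R 4.3.3 with limma 3.58.1. Intensities were transformed as log2(intensity + 16), so fold changes of dim genes are understated, and 64 Affymetrix control probe sets were left out of the tests. The column medians agreed within 0.0808 on the log2 scale, but the spread between the 25th and 75th percentile differed by 15.1% between the widest and narrowest array. The rule fixed in advance allowed 0.1 for the medians and 10% for the spread, so the arrays were quantile normalized. Means ± SD of intensity are of the deposited values, and log2 and fold changes are of the normalized ones with the offset. A change therefore need not equal the ratio of the intensities given beside it.

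Gene names came from the platform annotation supplied with the data. It gave exactly 1 symbol for 34945 probe sets, several for 932 and none for 9160. Of the first group, 34754 matched the mouse gene table of the GRCm38.p6 assembly by Entrez identifier, and 0 symbols needed updating. No coordinates are given, since no genome build is named for the arrays. Each gene was represented by the probe set with the highest mean over all 6 arrays, which left 18193 genes, 9010 of them with more than 1 probe set.

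Knockdown was compared with control by lmFit and eBayes with Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. The 33 gene lists, with 6 lists of markers of other cell types among them, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, each adjusted over the lists. Some genes are in more than 1 list. The groups, tests, lists, the alternatives that were planned and the rule for named genes were set before the data were examined. That rule picks Prdm2, a panel of 14 further genes, the 10 largest rises and falls among passing genes whose groups do not overlap and whose higher mean is above the median gene, and up to 4 passing members of each list, or up to 2 where none passed. Not all members it picks are printed, and counts of named genes are of all that it picks. Other genes that are named were chosen after their values were seen.

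The test was tried on simulated data with 18193 genes, 3 arrays per group and 200 changed genes. It recovered 57% of 2-fold and 88% of 4-fold changes, 100% of the recovered ones had the right sign, and 2.68% of its calls were unchanged genes. With no change simulated it made 0 calls. These rates describe the simulated data and were not measured on the real arrays. There, most probe sets lay below the offset, where a 2-fold change in intensity is smaller after the transformation. Control signals also differed between the real arrays. The rates are therefore not estimates of recovery or of false calls for the results below.

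Alternatives covered the normalization, the offset, a filter on low values, the variance model, the choice of probe set, the replicate number as a block, ordinary statistics without eBayes, array weights and leaving out each array. After the control probe sets had been seen, 3 more were added: the poly-A spike batch as a block, the 4 arrays of higher spike signal alone, and the Gapdh 5' to 3' ratio as a covariate. The comparison of a gene's probe sets with each other was also added after the values were seen. Where a list's camera adjusted p is given as a range over the alternatives, the range is at the preset correlation. It leaves out the estimated correlation and fry.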

Results

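Gene expression was measured on 6 Affymetrix mouse arrays, each hybridized with RNA from C2C12 cells, a mouse myoblast line that can be arrested in suspension and that fuses into myotubes when it differentiates. The cells carried an shRNA against PRDM2, a zinc finger protein with a PR/SET domain, or a control GFP shRNA, with 3 arrays in each group. Both kinds of cell had spent 48 hours in methylcellulose medium with 20% serum, which the labels describe as bringing them to G0, the quiescent state. The comparison asks which transcripts differ in quiescent myoblasts when PRDM2 is knocked down. After control probe sets were left out, 34945 probe sets carried exactly 1 gene symbol and represented 18193 genes. Median intensity lay between 10.6 and 12.1 on the 6 arrays, and between 55.1% and 58.2% of probe sets on each array were below an intensity of 16. The number of arrays limits the precision of every value below.

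The arrays differed in control signals that the groups do not account for. On control array 3, the Gapdh control probe set at the 5' end read 0.0992 of the probe set at the 3' end, against 0.704 to 1.14 on the other arrays, and the beta-actin ratio was 0.114, against 0.299 to 0.723. The Dap spike, a bacterial poly-A transcript added during labelling, gave intensities of 43.1 and 42.3 on control array 3 and knockdown array 3, and 160 to 350 on the other arrays. Differences are therefore also given within the 4 arrays of higher spike signal and between the 2 arrays of lower spike signal, 1 per group, where no test is possible. No pair of arrays held identical values. Correlations across genes were 0.963 to 0.986 within the groups and 0.942 to 0.968 between them. The leading principal component held 52.0% of the variance and separated the groups, with control arrays at -23.7, -22.2 and -37.6 and knockdown arrays at 26.6, 26.1 and 30.8.

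**Figure D1:**
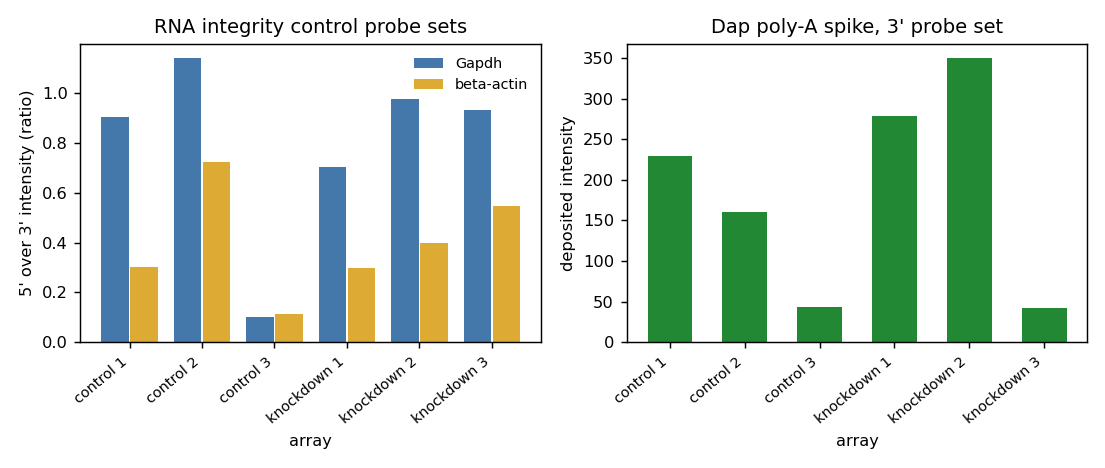
Control signals on each array: the left panel shows the ratio of 5' to 3' intensity for the Gapdh and beta-actin control probe sets, and the right panel the deposited intensity of the Dap poly-A spike. Control array 3 had ratios of 0.0992 and 0.114, and spike intensities were 43.1 and 42.3 on array 3 of each group.

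Prdm2, the gene the shRNA targets, had a lower mean signal in the knockdown at 2 of its 3 probe sets, and none of the 3 passed the test. The probe set that represents Prdm2 in the gene table read 86.2, 73.6 and 47.1 on control arrays 1 to 3 and 58.0, 51.5 and 29.0 on knockdown arrays 1 to 3. The mean intensity was 69.0 ± 20.0 in the control and 46.1 ± 15.2 in the knockdown (SD, n = 3 each), so that the knockdown stood at 66.9% of the control. The log2 difference was -0.51 (SE 0.214, limma adjusted p = 0.313), the values of the groups overlapped, and the exact two-sided permutation p was 0.2, where 3 arrays against 3 cannot give less than 0.1. Another probe set had means of 73.0 ± 39.2 and 37.5 ± 14.9, which is 51.3% of the control (log2 difference -0.75, limma adjusted p = 0.433 over all named probe sets). The remaining one was near background, at 6.51 ± 1.13 and 7.84 ± 0.535 (log2 difference 0.10). Prdm2 differed by -0.44 within the higher spike batch and by -0.64 between the 2 arrays of the lower one. Where these probe sets lie relative to the sequence the shRNA targets is not given in the sources used here.

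Knockdown cells had far more transcript of muscle structural genes than control cells and less of genes for cell division. Myh3, the embryonic myosin heavy chain, rose 30.3-fold from an intensity of 21.7 ± 7.64 to 1149 ± 146, and Acta1, skeletal alpha-actin, rose 22.8-fold from 80.6 ± 24.1 to 2261 ± 314 (SD, n = 3 each). Mki67, which encodes the proliferation marker Ki-67, was 5.78-fold lower, and Ccnd1, the G1 cyclin D1, was 4.89-fold lower. In all, 938 of 18193 genes passed the limma test at an adjusted p under 0.05, of which 539 rose and 399 fell. A change of at least 2-fold, on the transformed scale with its offset, was found for 503 of them, 281 up and 222 down. That share depended on the offset: with an offset of 1, 727 genes passed and 720 of them changed at least 2-fold. The 3 knockdown values lay apart from the 3 control values for all 938 of these genes, and for 20.6% of all genes, where chance gives 10%. Passing the test with 3 arrays per group nearly requires such separation, so that of the 938 is not added evidence. In the higher spike batch alone 358 genes passed. Without control array 1 the count was 544, and without knockdown array 1, 2 or 3 it was 444, 559 or 558.

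The 10 largest rises by the rule for named genes were those of Myh3, Tnnc2, Myl4, Acta1, Myl1, Mylpf, Apoe, Ttn, Myh7 and Actc1, with log2 changes from 4.92 down to 3.93. All but Apoe encode proteins of the sarcomere, the contractile unit of muscle. Apoe, which encodes the lipid carrier apolipoprotein E, rose by 4.03 (SE 0.243, limma adjusted p = 0.000448). Its deposited intensities were 21.6 ± 8.94 in the control and 605 ± 162 in the knockdown. The 10 largest falls were those of Nefl, Igsf5, Il33, Nt5e, Clu, Igfbp3, Stmn4, Rnf144b, Cdc20 and Sema3c. Nefl, the neurofilament light chain, fell by 3.82 (SE 0.123, limma adjusted p = 9.12e-05), from 229 ± 38.6 to 1.79 ± 0.635. Il33, a cytokine of the interleukin-1 family, fell by 3.52, Nt5e, the ecto-nucleotidase CD73, by 3.48, and Igfbp3, which binds insulin-like growth factors, by 3.15. Clu fell by 3.23 with a control intensity of 214 ± 185, and its limma adjusted p was 0.01 with all arrays and 0.0546 without knockdown array 1, with a range of 0.000272 to 0.125 over the alternatives.

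**Figure D2:**
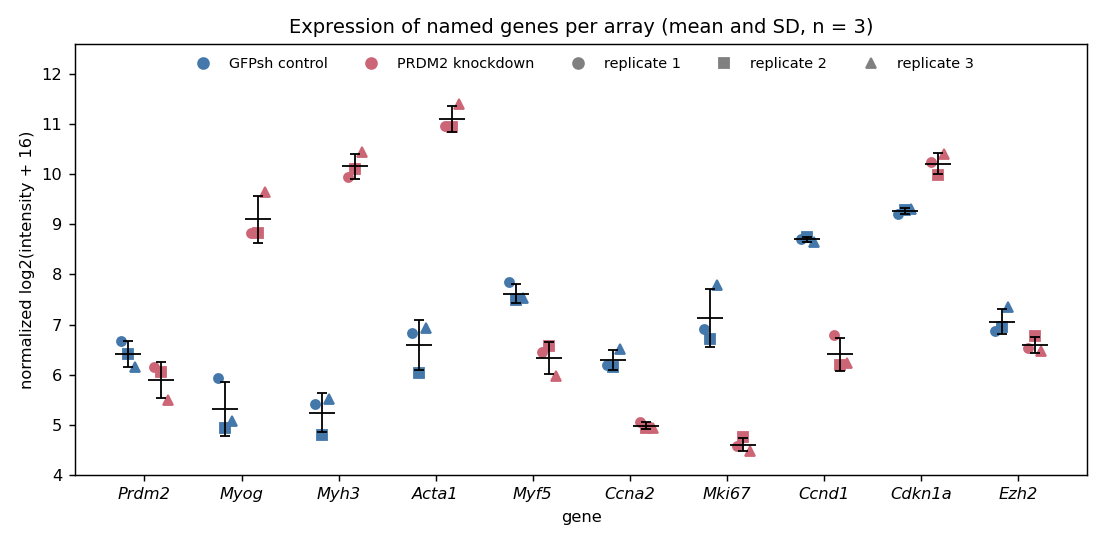
Normalized log2(intensity + 16) of 10 named genes on each array, with the control in blue, the knockdown in red, a marker shape for each replicate number, and horizontal lines for the group mean and SD (n = 3). Prdm2 differed by -0.51 with overlapping groups, while Myog, Myh3 and Acta1 were higher by 3.78, 4.92 and 4.51 and Ccnd1 and Mki67 fell by 2.29 and 2.53.

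Of the 33 gene lists, 9 passed limma's camera test with its preset correlation, 5 shifted up and 4 down. None of the 9 passed with an estimated correlation, where the smallest adjusted p was 0.109. The fry test, which asks whether a list's genes move on balance in 1 direction, passed 9 lists, 5 of them among the camera calls: sarcomere, G2 and mitosis, S phase, hypoxia and glycolysis, and myogenic regulators. The TGF-beta, repair, matrix and ribosome lists passed camera without passing fry, with fry adjusted p of 0.0792, 0.259, 0.0837 and 0.508. The neural, imprinted and adipocyte lists passed fry alone, each with an adjusted p of 0.0141, as did the NF-kB list, with 0.0261. Genes in at least 1 list made up 183 of the 938 changed genes, and 755 were in none.

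**Figure D3:**
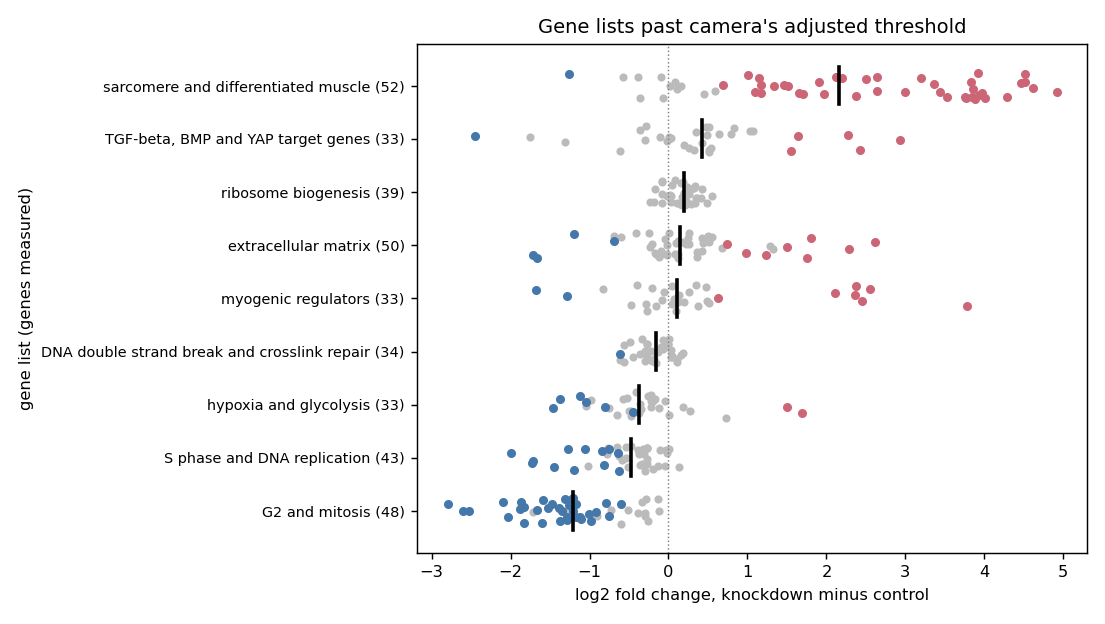
Log2 fold change, knockdown minus control, of each measured gene in the 9 lists past camera's threshold, with red for genes that rose, blue for genes that fell, grey for genes that did not pass and a black bar for the median. The medians run from 2.16 for the sarcomere list to -1.21 for the G2 and mitosis list.

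Genes of the sarcomere and differentiated muscle rose together. Of 52 measured members 40 rose, 1 fell and 11 did not pass (42 up and 1 down adjusted over the list alone), with a median log2 change of 2.16. With ordinary statistics in place of limma's moderated ones 24 rose. Troponin C of fast fibres, Tnnc2, rose by 4.61 and the myosin light chain gene Myl4 by 4.52. Among members named after their values were seen, the calcium handling genes Casq2, Atp2a1 and Ryr1 rose by 3.85, 3.53 and 2.51, and the myoblast fusion genes Mymx and Mymk by 3.20 and 3.00. Chrng, the fetal subunit of the acetylcholine receptor, rose by 2.37, whereas Chrna1 and Chrnd differed by 0.09 and 0.11 without passing. Desmin, Des, had intensities of 977 ± 125 and 789 ± 147 and did not pass (log2 difference -0.36, limma adjusted p = 0.459), and Tmod1, which caps thin filaments, fell by 1.26. The camera adjusted p was 2.08e-44, and the adjusted p = 0.109 with an estimated correlation. The list's median relative to the control mean was -0.16 to 0.09 on the control arrays and 1.99 to 2.23 on the knockdown arrays, and its median difference was 2.16 in the higher and 2.07 in the lower spike batch.

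The 2 probe sets of Ckm, the muscle creatine kinase, disagreed, which was looked at after their values were seen. The probe set that represents Ckm differed by -0.58 (limma adjusted p = 0.5), with means of 81.1 ± 33.7 and 51.0 ± 15.8. Its other probe set was higher by 2.69 (limma adjusted p = 0.00176 over all named probe sets), with means of 13.9 ± 4.52 and 186 ± 37.4. Across all genes, 124 had a representing probe set that did not pass and another that did, 15 of them in a gene list, and 29 genes had another passing probe set whose sign opposed that of the representing one. No gene had probe sets past the threshold in both directions.

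Genes of G2 and mitosis fell together. Of 48 measured members 34 fell, 0 rose and 14 did not pass (0 up and 42 down adjusted over the list alone), with a median log2 change of -1.21. With ordinary statistics 11 fell. Cdc20, an activator of the anaphase-promoting complex, fell by 2.79 (SE 0.282), Birc5, the chromosomal passenger survivin, by 2.60, Mki67 by 2.53 and Ccna2, cyclin A2, by 1.31. Anln, which encodes the cytokinesis protein anillin, fell by 2.09, with a limma adjusted p of 0.0127 that became 0.0582 without control array 1 and ranged from 0.000582 to 0.133 over the alternatives. For the list, camera gave an adjusted p of 1.03e-42, and the adjusted p = 0.109 with an estimated correlation. The list median was -0.09 to 0.15 on the control arrays and -1.13 to -1.32 on the knockdown arrays, and the difference was -1.07 in the higher and -1.46 in the lower spike batch. On control array 3, the array with the low 5' to 3' ratios, the list stood at 0.15, the highest of the 6, and without that array the median difference was -1.14 with 30 members lower past the threshold.

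Genes of S phase and DNA replication were lower too, with fewer members passing. Of 43 measured 12 fell, 0 rose and 31 did not pass (0 up and 19 down adjusted over the list alone), with a median of -0.48. Top2a, DNA topoisomerase II alpha, fell by 1.99 (SE 0.191, limma adjusted p = 0.00224). Mcm5, a subunit of the replicative helicase, fell by 1.73 with a limma adjusted p of 0.0111, which became 0.0545 without knockdown array 2 and 0.0566 without knockdown array 3, and ranged from 0.000582 to 0.122 over the alternatives. Ccne1, cyclin E1, differed by -0.59 and did not pass (limma adjusted p = 0.339). Camera gave the list an adjusted p of 5.01e-16, and the adjusted p = 0.229 with an estimated correlation. The median was -0.34 in the higher and -0.79 in the lower spike batch. The number of members that fell was 5 without control array 1 and 7, 4 or 5 without knockdown array 1, 2 or 3. It was 3 in the higher spike batch alone, and 0 with ordinary statistics in place of limma's moderated ones, where 20 were lower at an unadjusted p under 0.05.

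The list of cell cycle inhibitors and quiescence regulators showed no common shift, with 7 of 39 measured members up, 1 down and 31 not passing (7 and 1 adjusted over the list alone; camera adjusted p = 0.254). The cyclin-dependent kinase inhibitor Cdkn1c (p57) rose by 0.96, from an intensity of 4.48 ± 0.721 to 23.9 ± 1.87, and Cdkn1a (p21) rose by 0.94, from 585 ± 61.6 to 1185 ± 148 (SD, n = 3 each). The limma adjusted p of Cdkn1a was 0.00879, and 0.051 without knockdown array 1, within 0.00166 to 0.0763 over the alternatives. Rgs5, a regulator of G protein signalling, rose by 1.78, the forkhead factor Foxo1 by 1.35 and Spry1, an inhibitor of growth factor signalling, by 1.23. The other probe sets of Rgs5 differed by -0.10, 1.00 and 0.53 without passing, and with the mean of its probe sets its limma adjusted p was 0.0753. The retinoblastoma gene Rb1 and the inhibitor Cdkn1b (p27) differed by -0.06 and -0.10 without passing. The list's median was 0.02 in the higher and 0.08 in the lower spike batch.

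Among myogenic regulators, Myog, the transcription factor of terminal myoblast differentiation, rose 13.8-fold in the normalized values with the offset of 16. Its deposited intensities were 25.5 ± 16.2 in the control and 557 ± 179 in the knockdown. Myf5, a factor of undifferentiated myoblasts, was 2.44-fold lower in the normalized values, with intensities of 178 ± 39.2 and 67.5 ± 17.7. Myod1 differed by 0.47 without passing (limma adjusted p = 0.515), by 0.08 in the higher and 1.24 in the lower spike batch. Pax7, a marker of muscle stem cells, was near background in both groups, at 2.04 ± 1.14 and 3.46 ± 0.622. Of 33 measured members 7 rose, 2 fell and 24 did not pass (10 up and 2 down adjusted over the list alone), and with ordinary statistics 3 rose and 1 fell. Mef2c, a partner of myogenic factors, rose by 2.45, Fst, which encodes the myostatin antagonist follistatin, by 2.38, and Igf2, insulin-like growth factor 2, by 2.55. Cd34, a surface marker of quiescent muscle stem cells, fell by 1.68. The median was 0.11, or 0.07 in the higher and 0.14 in the lower spike batch. This list had a camera adjusted p of 0.00495, and the adjusted p = 0.159 with an estimated correlation.

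Hypoxia and glycolysis genes shifted down, with 6 of 33 measured lower, 2 higher and 25 not passing (3 up and 12 down adjusted over the list alone), and a median of -0.37. Pfkp, the platelet form of phosphofructokinase, fell by 1.37 and Adm, the peptide hormone adrenomedullin, by 1.46. The other probe sets of Pfkp differed by -0.30 and -0.86 without passing, and with the mean of its probe sets its limma adjusted p was 0.249. Car9, carbonic anhydrase 9, rose by 1.69 and Slc16a3, a lactate transporter, rose 2.83-fold. The glycolytic genes Ldha and Aldoa differed by -0.20 and 0.01 without passing. Adm had a limma adjusted p of 0.0357, which became 0.129 without control array 1, 0.108 without control array 3 and 0.108 and 0.0765 without knockdown array 2 and 3, within 0.00496 to 0.212 over the alternatives. As a list these genes had a camera adjusted p of 7.31e-06, and the adjusted p = 0.109 with an estimated correlation, with medians of -0.37 in the higher and -0.28 in the lower spike batch. The count of members that fell was 1 without control array 1, and 2 without control array 3 or any of the knockdown arrays. Ordinary statistics left 1 up and 1 down.

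In the list of TGF-beta, BMP and YAP target genes, 5 of 33 measured members rose, 1 fell and 27 did not pass (10 up and 3 down adjusted over the list alone), with a median of 0.42. Ordinary statistics left 0, with 10 up and 2 down at an unadjusted p under 0.05. Ankrd1, a YAP target also made in striated muscle, rose by 2.42 and the smooth muscle protein gene Tagln by 2.27, while Inhba, the activin A subunit, fell by 2.45. Thbs1, the matrix protein thrombospondin 1, rose by 2.94, with a limma adjusted p of 0.0136 that became 0.0598 without control array 1 and ranged from 0.000582 to 0.148 over the alternatives. Id1, a BMP target that blocks myogenic factors, differed by 0.48 without passing (limma adjusted p = 0.36). The camera adjusted p was 0.00302, and the adjusted p = 0.334 with an estimated correlation. It was 0.109 without control array 3, the array with the low 5' to 3' ratios, and 0.0932 in the higher spike batch, where the median was 0.18 against 0.59 in the lower. At the preset correlation it ranged from 0.000131 to 0.109 over the alternatives.

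Extracellular matrix genes went both ways, with 8 of 50 measured up, 4 down and 38 not passing (9 and 4 adjusted over the list alone), and with ordinary statistics 2 up and 0 down, or 11 and 4 at an unadjusted p under 0.05. Fbln5, an elastic fibre protein, rose by 2.61, the basement membrane gene Nid2 by 2.28, Col6a2, a collagen VI chain, by 1.80 and the proteoglycan gene Bgn by 1.75. Timp3, an inhibitor of matrix proteases, fell by 1.72 and Tnc, tenascin C, by 1.66. Fn1 and Col3a1 differed by 0.01 and -0.01. The median was 0.15, or 0.09 in the higher and 0.38 in the lower spike batch, and the camera adjusted p was 0.00495, with an adjusted p = 0.496 with an estimated correlation. Without control array 3 the camera adjusted p was 0.239, within 0.00023 to 0.501 over the alternatives. Members that rose numbered 5 without knockdown array 1 or 3, and members that fell numbered 1, 0, 2 and 1 without control array 1 and knockdown arrays 1, 2 and 3.

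The other lists past camera's threshold held few or no passing members. Of 34 genes for DNA double strand break and crosslink repair, 0 rose, 1 fell and 33 did not pass (0 and 1 adjusted over the list alone), with a median of -0.15. Brca1 was that member, at -0.61 (limma adjusted p = 0.024), with intensities of 21.3 ± 3.68 and 8.24 ± 2.06. It passed only with all arrays or without knockdown array 3, with adjusted p from 0.0654 to 0.0974 without any of the others. Over all alternatives its limma adjusted p ran from 0.00948 to 0.211, the highest with the mean of its probe sets. The other probe sets of Brca1 differed by 0.07, -0.01 and -0.29 without passing. The repair list had a camera adjusted p of 0.00495, and the adjusted p = 0.496 with an estimated correlation. Its camera call was lost without control array 3 (adjusted p = 0.05), with the filter on low values (0.161, median -0.04) and in the higher spike batch (0.0947). The median was -0.09 in the higher and -0.33 in the lower spike batch. At the preset correlation the list's camera adjusted p ranged from 0.00129 to 0.161 over the alternatives. Of 39 ribosome biogenesis genes none passed limma's test, 0 adjusted over the list alone, and the median was 0.19, or 0.30 in the higher and -0.0050 in the lower spike batch. Relative to the control mean, this list's median was -0.02, -0.20 and 0.28 on control arrays 1 to 3. On knockdown arrays 1 to 3 it was 0.17, 0.11 and 0.35, so the groups overlapped. For ribosome biogenesis the camera adjusted p was 0.00972, and the adjusted p = 0.711 with an estimated correlation. At the preset correlation it was 0.0615, 0.185 and 0.165 without control array 1, control array 2 and knockdown array 3, within 1.85e-05 to 0.185 over the alternatives.

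No member of the list of Polycomb and histone methyltransferases passed, with 46 measured (0 adjusted over the list alone; camera adjusted p = 0.562). Ezh2, the catalytic subunit of Polycomb repressive complex 2, had intensities of 113 ± 10.8 in the control and 83.5 ± 10.4 in the knockdown (log2 difference -0.47, limma adjusted p = 0.197), and Aebp2, an accessory subunit, differed by -0.40. In the PRDM family, 1 of 12 measured members rose, 0 fell and 11 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.83). Prdm1, also called Blimp1, was that member, at 0.73 (limma adjusted p = 0.0338), and it lost the call without each array but control array 1, with adjusted p from 0.0667 to 0.142, and 0.026 to 0.238 over all alternatives.

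Markers of other cell types were examined in 6 lists. None passed camera in the planned fit, while the adipocyte and neural lists passed fry, and both also passed camera under some alternatives. Of 15 adipocyte markers 4 rose, 1 fell and 10 did not pass (4 and 2 adjusted over the list alone; camera adjusted p = 0.0601, and 0.0127 to 0.13 over the alternatives). Lipoprotein lipase, Lpl, rose by 3.10, the transcription factor Cebpa by 2.95 and the fatty acid transporter Cd36 by 1.83. The adipocyte genes Pparg, Fabp4 and Adipoq differed by -0.38, 0.16 and 0.05 without passing. Of 18 neural and Schwann cell markers 1 rose, 3 fell and 14 did not pass (1 and 3 adjusted over the list alone; camera adjusted p = 0.0553, 0.0288 as deposited without quantile normalization, and 0.0212 to 0.135 over the alternatives). Stmn2, a neuronal microtubule regulator, rose by 1.95 while Nefl fell by 3.82, Tubb3 by 0.96 and S100b by 0.90. Tubb3 lost limma's call without each of the knockdown arrays (adjusted p from 0.0650 to 0.0756). The neural list's mean change was -0.28 and its median -0.10, and how far its result rests on Nefl was not tested. Of 16 osteoblast and cartilage markers 1, Phex, rose by 1.83 and 15 did not pass (camera adjusted p = 0.795). Of 15 fibroblast and tendon markers 1, the tendon factor Scx, fell by 1.35 and 14 did not pass (camera adjusted p = 0.973), with limma adjusted p values for Scx of 0.0655 without control array 1 and 0.0546 without knockdown array 1, within 0.00222 to 0.129 over the alternatives. Of 16 endothelial markers 1, Flt1, fell by 1.02 and 15 did not pass (camera adjusted p = 0.254). None of 16 macrophage and blood cell markers passed (camera adjusted p = 0.791). Adjusted over the list alone, the counts up and down were 1 and 0 for the osteoblast, 1 and 1 for the fibroblast, 0 and 1 for the endothelial and 0 and 0 for the macrophage list.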

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

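The tests on Prdm2 and on other splits of the arrays were chosen after those results had been seen; the tests on the muscle and mitosis lists were written down before their values were computed.

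Probe sets without a single gene symbol were tested outside the gene comparison. Of 10092 tested with limma, 84 passed at an adjusted p under 0.05, 43 higher and 41 lower in the knockdown, and 649 were under an unadjusted p of 0.05. With the replicate number as a block 45 passed. A probe set without a symbol was 9.98-fold higher, and another was 12.3-fold lower. A probe set listed for both Myh7 and Myh6 was higher by 2.94 on the log2 scale. These 3 were chosen after their values were seen.

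Muscle genes were higher in the knockdown, by a list median of 2.16. An effect of control array 3, whose 5' to 3' ratios were low, was argued against: without it, the smallest difference between a knockdown and a control array, as the median over members, was 2.00. The quantile normalization was argued against by a smaller median of 2.20 without it. Each spike batch holds arrays of both groups, so a shift shared by a batch cancels in the comparison. The smaller within-batch median, 2.07, therefore shows only that the difference stood in each batch. A candidate explanation is that the shRNA against PRDM2 let cells in suspension enter differentiation, but this stays a hypothesis found on these data, and entry into differentiation itself was not tested. Effects of the shRNA sequence or of the pool besides PRDM2 were not tested, as the labels name 1 kind of PRDM2 shRNA.

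G2 and mitosis genes were lower in the knockdown, by a list median of -1.21. Without control array 3, the array with the low 5' to 3' ratios, the smallest fall between a knockdown and a control array, as the median over members, was -1.02. The smaller median without quantile normalization was -1.16, so control array 3 and the normalization were each argued against as the whole cause. Each spike batch holds arrays of both groups, so a shift shared by a batch cancels in the comparison. The smaller within-batch median, -1.07, therefore shows only that the fall stood in each batch. A lower share of cycling cells in the knockdown pool may account for the change as a hypothesis. The share of cycling cells was not measured, and pool differences besides PRDM2 stay open and untested.

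Prdm2 itself did not pass. In limma's fit over all named probe sets, the adjusted p of the 3 probe sets was 0.400, 0.766 and 0.433. Their unadjusted p was 0.0529, 0.281 and 0.0619, so another choice of probe set would not have passed. In the gene table the representing probe set had a limma unadjusted p of 0.0488 with an adjusted p of 0.313. Control array 3 with its low 5' to 3' ratios and the spike batches cannot be told apart from spread between arrays as the reason. The adjusted p was 0.256 without control array 3 and 0.0730 with the spike batch as a block, within 0.0730 to 0.595 over the alternatives, and the unadjusted p was under 0.05 in both of these. Whether the shRNA acts on the part of the transcript these probe sets read was not tested, and whether protein fell was not measured here.

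The real grouping of the 6 arrays gave 938 changed genes by limma, and the highest of the other splits into 3 and 3 gave 0. Only 1 of the 10 splits, the real one, reached 938. Each other split mixes the groups, so a difference between the groups enters its residual spread, and its 0 is not a count of false calls. The share cannot be less than 0.1, so 10 splits are too few for a share under 0.05.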

How the results depend on the processing

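Changed genes numbered 938, with 539 up, 399 down and 503 at 2-fold or more. Ordinary statistics without eBayes gave 211, 141, 70 and 153, and array weights gave 1615, 893 and 722 in the first 3 of these. The higher spike batch alone, with fewer arrays, gave 358, 210, 148 and 317. Leaving out each array gave totals of 444 to 815, 245 to 421 up, 199 to 394 down and 363 to 512 at 2-fold. Totals under the other alternatives ran from 712 to 1014. Their lowest count at 2-fold or more was 351 of 900, with the mean of a gene's probe sets. Their highest was 720 of 727, with an offset of 1. No passing gene named by the rule and none of the 9 lists past camera turned in sign under these alternatives, though the ribosome biogenesis median was -0.0050 between the 2 arrays of the lower spike batch. Rb1, Cdkn1b and medians near 0 of lists that did not pass did turn; among the 938 genes, 1 changed sign with the mean of a gene's probe sets and 6 with probe sets of suffix _x_at or _s_at left out. The share of calls that were rises was 57.5%, and ran from 51.7% without control array 2 to 66.8% with ordinary statistics.

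With the replicate number as a block, 712 genes passed, 409 up, 303 down and 458 at 2-fold, and 11 lists. The replicate number was left out of the planned fit before the data were examined. Same-numbered arrays deviated together with correlations of 0.34, 0.01 and 0.12, and differently numbered ones with correlations from -0.39 to 0.16. Control arrays 1 and 3 correlated best with the knockdown array of their own number, and control array 2 with knockdown array 3, at 0.16. Array 3 of each group also shared the low Dap spike signal, at 43.1 and 42.3 against 160 to 350 on the other arrays. Number 3 thus went with a shared control signal in both groups, but whether all the numbers mark pairs stays open.

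The count of lists, 9, was 0 with an estimated correlation and 6 to 11 without single arrays; every probe set on its own was not run for lists. The lists for sarcomere, G2 and mitosis, S phase, hypoxia and myogenic regulators kept camera's call under every setting of the fit. Prdm2 stayed between -0.66 and -0.31 without single arrays, and its adjusted p was 0.0730 to 0.595 over all alternatives. Of 92 passing named genes, 65 kept the call without each array and 27 lost it without at least 1, while 65 lost it with ordinary statistics and 38 in the higher spike batch alone. With ordinary statistics 24 sarcomere members rose, 11 G2 and mitosis members fell, 3 myogenic regulators rose and 1 fell, 2 matrix genes rose, and 1 hypoxia and glycolysis gene rose and 1 fell. The TGF-beta and repair lists then had 0 passing members, with 10 up and 2 down, and 0 up and 6 down, at an unadjusted p under 0.05. Passing probe sets without a single symbol numbered 84, or 45 with the replicate block and 95 with a trended, robust fit, the alternatives run for them. The cause was not tested. Low signal limits dim genes, since 55.1% to 58.2% of probe sets on each array lay below the offset.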

Other observations

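Further lists, none of which passed camera in the planned fit, held single genes that changed. In the list of immediate early genes, 5 of 29 measured rose, 3 fell and 21 did not pass (8 and 4 adjusted over the list alone; camera adjusted p = 0.277). Zfp36, which destabilizes inflammatory mRNAs, rose by 1.55 and Egr2 by 1.54, while Atf3, a stress-induced factor, fell by 2.12 and Jund by 1.45. In the list of NF-kB and inflammatory genes, 3 of 33 rose, 2 fell and 28 did not pass (4 and 2 adjusted over the list alone; camera adjusted p = 0.133). Cxcl12, a chemokine made by stromal cells, rose by 2.88 and Cxcl5 by 2.75, whereas Il33 fell by 3.52. Deposited intensities of Cxcl12 were 5.65 ± 0.602 in the control and 149 ± 21.5 in the knockdown (SD, n = 3 each). The limma adjusted p of Cxcl5 was 0.00893, and 0.051 without knockdown array 1, within 0.000298 to 0.117 over the alternatives. That list passed without control array 2 (camera adjusted p = 0.0119, the lowest of a range up to 0.306). Among 22 imprinted growth genes 3 rose, 0 fell and 19 did not pass (3 and 0 adjusted over the list alone). These were Igf2, by 2.55, Ndn, by 1.97, and Cdkn1c, by 0.96. The camera adjusted p was 0.0553 for the imprinted list, and 0.044 with the spike batch as a block, 0.0164 without control array 2 and 0.0234 without knockdown array 1, within 0.00468 to 0.153 over the alternatives.

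In the Notch pathway 3 of 25 measured genes rose, 0 fell and 22 did not pass (4 and 1 adjusted over the list alone; camera adjusted p = 0.795). Hey1, a Notch and BMP target, rose by 1.56 and the receptor Notch1 by 0.88. In the Wnt pathway 3 of 36 rose, 4 fell and 29 did not pass (7 and 6 adjusted over the list alone; camera adjusted p = 0.952). The receptor Fzd1 rose by 2.03, and the secreted modulators Sfrp4 and Ccn5 fell by 1.51 and 1.26. Among integrins, focal adhesion and actin cytoskeleton genes 4 of 43 rose, 4 fell and 35 did not pass (5 and 7 adjusted over the list alone; camera adjusted p = 0.795). Myl9, a myosin light chain of smooth muscle, rose by 2.49. Itga4 rose by 0.99 at its representing probe set, while its other probe sets differed by -0.42, -0.06, -0.06 and 0.02 without passing. With the mean of its probe sets the limma adjusted p of Itga4 was 0.809. That list's median was 0.07 with all arrays, but -0.20 in the higher spike batch, where it passed (camera adjusted p = 0.0357, the lowest of a range up to 0.963), and 0.17 in the lower. Among p53 target genes 3 of 30 rose, 2 fell and 25 did not pass (5 and 2 adjusted over the list alone; camera adjusted p = 0.795), with Cdkn1a up by 0.94 and Ckap2, also in the mitosis list, down at -0.75. Of 33 apoptosis regulators 1 rose, 1 fell and 31 did not pass (2 and 1 adjusted over the list alone; camera adjusted p = 0.795). These were Casp1, at 0.49, and Apaf1, at -0.56. Both lost limma's call whichever array was left out, with adjusted p of 0.0779 to 0.162 for Casp1 and 0.0533 to 0.112 for Apaf1, and ranges of 0.018 to 0.162 and 0.0086 to 0.22 over all alternatives.

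Of 20 cholesterol biosynthesis genes 1 rose, 1 fell and 18 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.254). Sqle, squalene epoxidase, fell by 1.37, and Insig1, a regulator of sterol synthesis, rose by 1.24, with a limma adjusted p of 0.0257 that was 0.0913 to 0.101 without each of the knockdown arrays, within 0.00621 to 0.174 over the alternatives. Of 35 lysosome and autophagy genes 1 rose, 0 fell and 34 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.114), and the list passed without control array 2 (adjusted p = 0.0164, the lowest of a range up to 0.723). Of 32 genes of the unfolded protein and ATF4 response 1 rose, 0 fell and 31 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.795). In limma's test none passed among 35 interferon response, 41 oxidative phosphorylation, 31 proteasome and 30 Hox genes, over all genes or adjusted over the list alone, with camera adjusted p of 0.795, 0.83, 0.226 and 0.83. The median of the oxidative phosphorylation list was 0.12 in the higher and -0.23 in the lower spike batch. Camera's direction was opposite in sign to the median for the integrin, Polycomb, macrophage, osteoblast, Wnt and fibroblast lists. It was opposite to the mean for the integrin, interferon and fibroblast lists.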
